A study of Caenorhabditis elegans with 8 samples.

How the data were processed

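Small RNAs of whole Caenorhabditis elegans worms were sequenced in 8 libraries from 4 genotypes, 2 libraries each. Per the labels' protocols, total RNA was extracted with Trizol, small RNAs were enriched on a column, and the samples were treated with the polyphosphatase PIR-1, which removes 5′ phosphates of triphosphorylated small RNAs so that they can be ligated. Adaptors were then ligated and the cDNA was amplified and sequenced. The 5′ adaptor carried a barcode. Per the submitters' processing notes, cutadapt 1.18 and Bowtie 1.2.1.1 were used; their settings, the aligned genome build and the treatment of reads with several matches are not given in the sources used here.

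The authors deposited 1 table of 9742 piRNAs (21U-RNAs) with 1 column per library in RPM, reads scaled to a library total of 1e6. Every positive value was a whole multiple of the smallest value of its library (tolerance 0.01 reads), so that 100% of the positive values gave whole reads. The number 1e6 divided by that smallest value gave a whole number in each library, which is taken here as the read total to which the authors scaled. It ranged from 341001 to 5608712 reads. What reads that total covers is not stated, so an RPM value is a share of an RNA pool whose make-up was not analysed here. No column of values was left unused. The design written before the data were examined allowed for either counts or normalized values; the table held RPM, so the tests for normalized values were used.

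Positions were taken from the table and compared with the piRNA genes of the Ensembl release 115 annotation of WBcel235. Coordinates and strand matched for 9620 of the 9742 listed piRNAs, and 122 did not match; the annotation holds 15363 piRNA genes. Names are those of the annotation where a position matched and otherwise those of the table. The annotation also gave overlapping genes, exons and microRNA arms. No genome sequence was used, so the lists planned on the upstream motif, on its first base and on the first base of the piRNA were not run. Lists of other small RNA classes and of type I and type II piRNAs were not run either, since the table does not mark them. For the same reason cell type markers were not analysed here.

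The main test for single piRNAs was limma 3.58.1 in R 4.3.3, with a trended prior, on log2(RPM + 1), over all 8 libraries with genotype as the only factor and no rescaling between libraries. A piRNA was tested when its mean over the 8 libraries was at least 1 RPM, which left 695. P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. All tests were two-sided. Fold changes on this scale understate the change of low piRNAs. The fit shares the spread of a piRNA across the genotypes, and genotypes at 0 add none to it. SE and p can therefore depend on single reads in other genotypes. 21ur-5695 and 21ur-6307, both without a kin-3 read, had SE 0.0415 and 0.335 in kin-3 against WT. Because RPM is not a count, edgeR 4.0.16 (quasi-likelihood test) on the recovered reads was an alternative; it used the scaling totals as library sizes. Library totals and numbers of detected piRNAs were compared by exact permutation tests over the 4 genotypes and for WT against the other 6 libraries (28 splits). For 2 libraries against 2 the smallest exact p is 0.333, so pairs of genotypes are given as values. Lists were compared with the other tested piRNAs by camera (correlation 0.01), again with an estimated correlation, and by fry, which tests whether a list moves one way. Other alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 10 RPM, TMM rescaling, the replicate block, fits of only the genotypes compared, and leaving out each library in turn.

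Counting intervals are exact 95% intervals on pooled reads (Poisson for a level, conditional binomial for a ratio). The floor for a piRNA with no read is 3 reads of a genotype's pooled scaling total: 3.32 RPM for kin-3, 1.80 RPM for prg-1 and 0.274 RPM for prde-1. Reads were not tagged with molecular identifiers as far as the labels say, so intervals and floors cover counting error only. Deeper prde-1 libraries therefore bound low levels more tightly than the kin-3 libraries.

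The piRNAs named were chosen by a rule fixed before the data were examined: per mutant, the 10 largest falls and the 10 largest rises past the threshold with both mutant values beyond both WT values and a mean of at least 10 RPM over the 8 libraries, the 10 piRNAs with the highest mean, and 21ur-1 and 21ux-1 where listed. 21ux-1 was not among the piRNAs analysed here. Other piRNAs that are named were chosen after their values were seen.

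The labels do not say whether libraries of a genotype came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. A chi-square test of the recovered reads of piRNAs with at least 10 reads gave no p under 0.05: p was 0.132 for WT (647 piRNAs), 0.0806 for prde-1 (17), 0.596 for prg-1 (4) and 0.236 for kin-3 (4). For prg-1 and kin-3 4 piRNAs are too few to show a difference. The summed chromosome IV reads without 21ur-1430, tested after the data were seen, differed between the kin-3 libraries (27 and 23 reads, 79.2 and 40.9 RPM, exact binomial p = 0.0198) and not detectably within WT, prde-1 and prg-1 (0.0613, 0.499 and 0.193). No pair was identical, and each library was kept as 1 replicate.

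The limma procedure was tested on simulated reads for the 695 piRNAs. Of 100 piRNAs lowered 8-fold it called 80 for kin-3, 77 for prde-1 and 81 for prg-1, of 100 raised 4-fold 91, 97 and 94, and of 495 unchanged ones 10, 2 and 3. When 495 were lowered 100-fold it called 478, 485 and 485 of them, and 15, 4 and 12 of 200 unchanged ones. Camera called a simulated list of 45 lowered piRNAs in 20 of 20 simulations for each mutant, and a list of 45 unchanged ones in 1 for kin-3, 3 for prde-1 and 0 for prg-1.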

Results

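The series asks whether casein kinase II promotes the production of piRNAs, the germline small RNAs of about 21 nt that in worms begin with U and are bound by the Piwi protein PRG-1. Small RNAs of whole worms were profiled in WT, in prde-1, in prg-1 and in kin-3 worms, with 2 libraries each. PRDE-1 is a component of the upstream sequence transcription complex that acts at piRNA genes, PRG-1 is the piRNA-binding Argonaute, and KIN-3 is the catalytic subunit of casein kinase II. The kin-3 worms were cultured with 500 µM IAA (auxin) and the other worms were untreated, so the kin-3 comparisons carry the genotype and the IAA together. The 3 genotypes other than WT are called mutants here for short, which for kin-3 means the genotype with IAA. Transcripts of the 3 genes themselves were not measured. The scaling totals were 1342764 and 913321 reads for WT, 5337646 and 5608712 for prde-1, 969718 and 699884 for prg-1, and 341001 and 562081 for kin-3. Of these, 17895 and 11907 reads were assigned to listed piRNAs in WT, 2057 and 2257 in prde-1, 222 and 156 in prg-1, and 82 and 117 in kin-3.

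Nearly all piRNA reads were lost in each of the 3 mutants. Listed piRNAs summed to 13182 ± 205 RPM (SD, n = 2) in WT, against 224 ± 22.8 in kin-3, 394 ± 12.04 in prde-1 and 226 ± 4.27 in prg-1 (each SD, n = 2). These are 1.70%, 2.99% and 1.71% of the WT level, or 58.8-fold, 33.5-fold and 58.3-fold lower. On chromosome IV, which carries the piRNA clusters, the remaining level without the locus 21ur-1430 was 0.459% of WT in kin-3, 0.185% in prde-1 and 0.457% in prg-1. A read was found for 3818 and 3220 piRNAs in the WT libraries, for 36 and 36 in kin-3, for 127 and 130 in prde-1, and for 75 and 46 in prg-1. WT differed from the other 6 libraries in the total and in the number detected (exact permutation p = 0.0357 each, the smallest that 28 splits can give). Over the 4 genotypes the exact permutation p was 0.0286 for the total and 0.00952 for the number detected. The number detected depends on depth: thinned to 341001 reads, 1890 ± 7.76 piRNAs were expected in WT, 30.8 ± 7.38 in kin-3, 19.5 ± 0.529 in prde-1 and 28.9 ± 4.80 in prg-1 (SD, n = 2), so the order of prde-1 and kin-3 turned. At or above 1 RPM, WT libraries held 2188 and 3220 piRNAs; 1 read is worth more than 1 RPM in 5 of the 8 libraries, so this threshold is not the same in all of them.

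**Figure D1:**
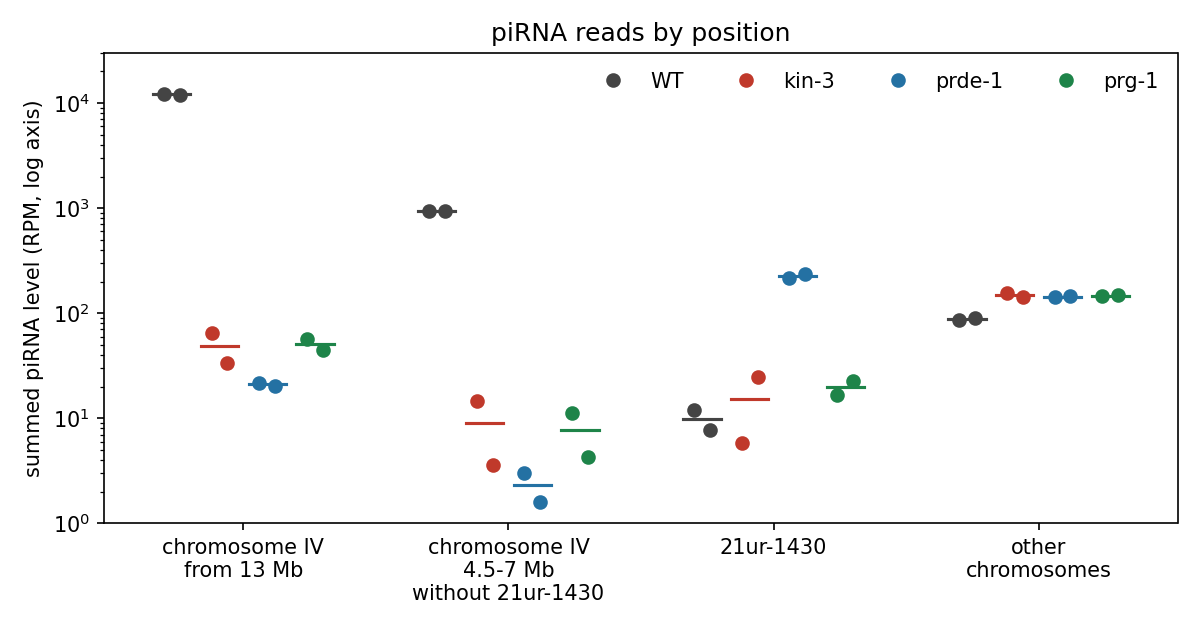
Summed piRNA level per library in RPM on a log axis, for the chromosome IV cluster from 13 Mb, the chromosome IV cluster at 4.5 to 7 Mb without 21ur-1430, the locus 21ur-1430, and all other chromosomes. Each point is 1 library and each line the mean of 2; the large cluster falls from 12255 and 11973 RPM in WT to 64.5 and 33.8 RPM in kin-3, while the other chromosomes lie between 142 and 155 RPM in all 6 mutant libraries.

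The comparison of kin-3 with WT addresses whether worms of this casein kinase II genotype make piRNAs. Of the 10 piRNAs with the highest WT means, 9 had no kin-3 read, and 21ur-13680, at 70.0 RPM in WT, had 2 (pooled ratio 31.4, 95% interval 8.56 to 262). 21ur-6307 (chromosome IV 14577635 to 14577655, minus strand, in no coding gene) stood at 202 ± 12.8 RPM (SD, n = 2) in WT and had no read in either kin-3 library, at least 60.7-fold lower against the pooled floor of 3.32 RPM (log2 fold change -7.66, SE 0.34, limma adjusted p = 5.5e-06). 21ur-5695 (chromosome IV 14310785 to 14310805, minus strand, antisense within an intron of Y64G10A.7) stood at 186 ± 7.52 RPM in WT and was at least 56.1-fold lower. The other piRNAs among the 10 largest falls, 21ur-2934, 21ur-2822, 21ur-7923, 21ur-5410, 21ur-2741, 21ur-7986, 21ur-5714 and 21ur-3502, ranged from 64.7 to 93.5 RPM in WT and had no kin-3 read, at least 19.5-fold to 28.1-fold lower. Of the 695 piRNAs tested, limma called 680 lower and 2 higher in kin-3. As many as were called, 682 in kin-3, had an unadjusted p under 0.05, with 689 in prde-1 and 684 in prg-1. For calls near the threshold the adjusted p is therefore close to the unadjusted one. It is no error rate among the few rises. 21ur-9719 (X 9072394 to 9072414, minus strand, antisense to an exon of the long noncoding RNA gene linc-22) rose from 13.4 ± 4.24 to 79.6 ± 11.9 RPM (5.93-fold; log2 fold change 2.51, SE 0.27, limma adjusted p = 3.0e-04, both libraries higher). Without the filter on low values, where 4878 piRNAs are tested, its adjusted p was 0.0768, and over the alternatives it ranged from 1.8e-11 to 0.0768. 21ur-9823 (III 1371141 to 1371161, antisense to an exon of linc-24) was the other rise, from 1.47 to 9.74 RPM (log2 fold change 2.18, SE 0.34, adjusted p = 0.0015), on 9 reads against 3 in WT (pooled ratio 7.49, interval 1.87 to 43.0). Its call ended under edgeR with the replicate block, chosen after seeing the data (edgeR adjusted p = 0.157, log2 fold change 2.91). Of the tested piRNAs, 663 had no kin-3 read and 26 had 1 to 3.

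The comparison of prde-1 with WT gives the loss caused by a lesion in the transcription complex itself. Its 10 largest falls again lay on chromosome IV from 13 Mb. 21ur-5695 had no read in either prde-1 library, at least 680-fold lower than in WT, and 21ur-6307 had 1 read in prde-1 against 459 in WT, a pooled ratio of 2227 (95% interval 398 to 88152). 21ur-13680 (chromosome IV 17029029 to 17029049, in a coding exon), at 70.0 ± 3.18 RPM in WT, was at least 255-fold lower. Limma called 683 of the 695 lower and 6 higher. The largest rise was at 21ur-1430 (chromosome IV 5566428 to 5566448, plus strand), from 9.79 ± 3.01 RPM in WT to 226 ± 11.5 RPM in prde-1 (SD, n = 2; 23.0-fold; log2 fold change 4.42, SE 0.65, limma adjusted p = 0.0012). This locus lies within the annotated mir-790 precursor on the same strand, and its 3′ end is that of an annotated 22 nt microRNA arm that begins 1 nt upstream. 21ur-10824 (III 2295350 to 2295370, sense to the 3′ UTR of Y54F10BM.9) rose 3.47-fold from 11.98 ± 0.0907 to 41.6 ± 6.04 RPM, and 21ur-10492 (II 13247294 to 13247314, antisense to an exon of F15D4.5) rose 2.32-fold from 16.8 ± 3.63 to 39.0 ± 4.47 RPM. 21ur-9719 rose 2.16-fold to 29.0 ± 0.792 RPM (limma adjusted p = 0.0105); leaving out prde-1 replicate 1 or 2 ended this call (adjusted p 0.0648 and 0.0767), and so did dropping the filter (0.287; range over the alternatives 5.5e-05 to 0.287). 21ur-15587, on chromosome I sense within an intron of ccct-1 and antisense to a pseudogene exon, and 21ur-9823 were the other rises, to 6.67 and 3.49 RPM (adjusted p = 0.0181 and 0.0436). The call of 21ur-15587 rests on 73 reads against 1 in WT, and ended with pseudocount 0.1 (0.0663) and without WT replicate 2, prde-1 replicate 1 or prde-1 replicate 2 (0.0964, 0.0667 and 0.0648). That of 21ur-9823 rests on 38 reads against 3 (pooled ratio 2.61, 95% interval 0.828 to 13.2). Among the alternatives that ended it were edgeR (0.0765), pseudocount 0.1 (0.0646), no filter (0.0651), only prde-1 and WT fitted (0.0865), and any library left out except WT replicate 2 (0.0576 to 0.431). TMM rescaling, which moved the median of all tested piRNAs from -3.06 to -2.12, gave 10 rises in prde-1 instead of 6. Its factors, by which the levels are divided, were 0.176 and 0.144 in prde-1 and 1.08 to 2.22 in the other libraries. It thus raised prde-1 against all other genotypes.

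The comparison of prg-1 with WT gives the loss when the binding protein is mutated. The same 10 piRNAs as in prde-1 had the largest falls: 21ur-5695 had no read, at least 104-fold lower, 21ur-6307 had 1 read against 459 in WT (pooled ratio 340, 95% interval 60.7 to 13446), and the rest of the 10 had no read and were at least 37.6-fold to 52.0-fold lower. Limma called 681 of the 695 lower and 3 higher. 21ur-9719 rose 6.87-fold to 92.3 ± 10.9 RPM (log2 fold change 2.72, SE 0.27, limma adjusted p = 2.1e-04; 0.0573 without the filter, the highest over the alternatives, the lowest being 1.4e-18). 21ur-10824 rose 1.73-fold to 20.7 ± 3.04 RPM (adjusted p = 0.0150). That call ended with edgeR on the recovered reads (adjusted p = 0.0740), without the filter (0.0757) and without WT replicate 1, WT replicate 2 or prg-1 replicate 2 (0.0982, 0.0888 and 0.0752); the range over the alternatives was 0.00997 to 0.141. 21ur-9823 was the other call (adjusted p = 0.0438), on 6 reads against 3 in WT (pooled ratio 2.70, 95% interval 0.577 to 16.7). Among the alternatives that ended it were edgeR (0.159), pseudocount 0.1 (0.0647), no filter (0.0653), TMM rescaling (0.0517), only prg-1 and WT fitted (0.0935), and any library left out except WT replicate 2 (0.0582 to 0.432). 21ur-1430 stood at 19.7 ± 4.498 RPM in prg-1 (adjusted p = 0.208) and at 15.4 ± 13.5 RPM in kin-3 (adjusted p = 0.633), neither past the threshold. Without kin-3 replicate 1 the adjusted p of 21ur-1430 was 0.0204 in kin-3 and 0.0281 in prg-1; without kin-3 replicate 2 it was 0.0256 in prg-1, and with only prg-1 and WT fitted 0.0453. Over the alternatives it ranged from 0.0204 to 0.963 in kin-3 and from 0.0256 to 0.495 in prg-1. The kin-3 libraries lay at 5.87 and 24.9 RPM, and without kin-3 replicate 2 the log2 fold change of 21ur-1430 in kin-3 turned from 0.33 to -0.62 (adjusted p = 0.139). 21ur-1 was listed at 0 in all 8 libraries.

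**Figure D2:**
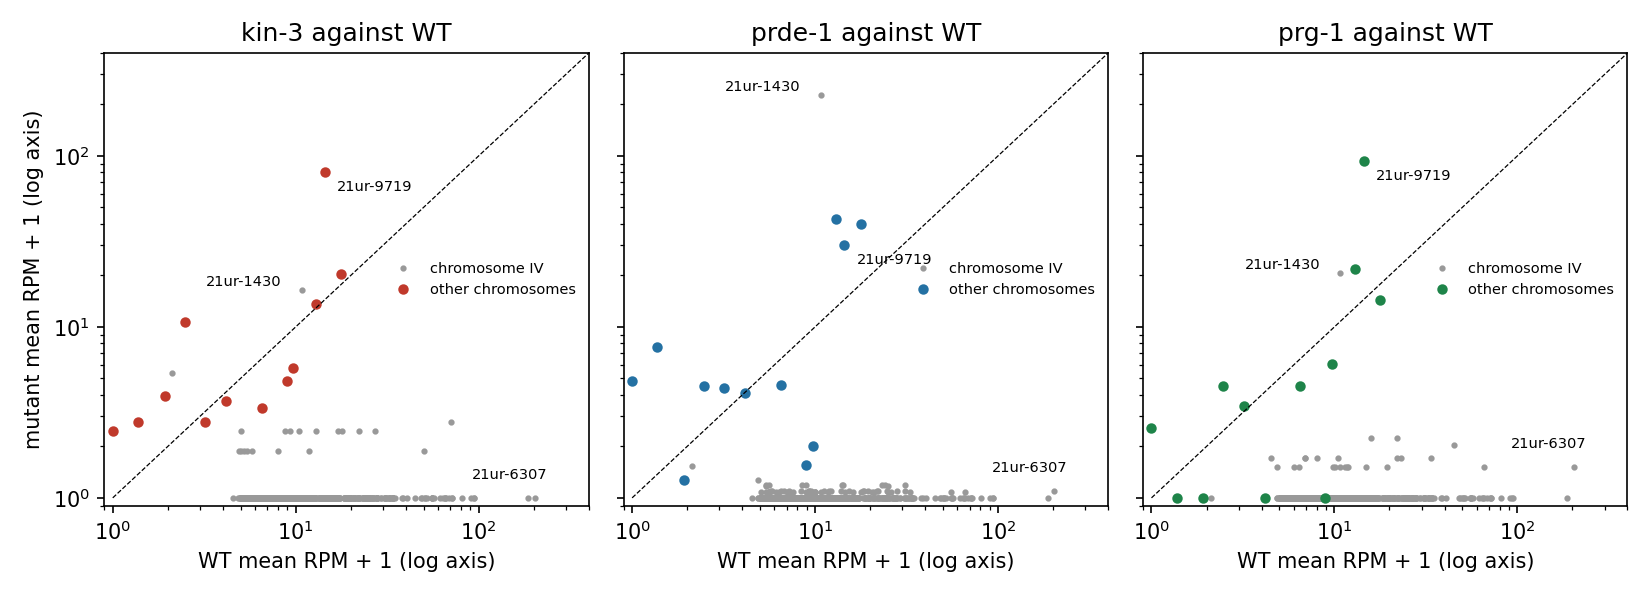
Mean RPM + 1 of the 695 tested piRNAs in each mutant against WT, both on log axes, with the line of equal levels dashed. Grey points are chromosome IV loci and coloured points the 12 loci on other chromosomes; most chromosome IV loci lie at the bottom, while 21ur-9719 lies above the line in each panel and 21ur-1430 reaches 226 RPM in prde-1.

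Position separated the piRNAs that fell from those that did not. Of the 638 tested piRNAs on chromosome IV from 13 Mb, 635 fell in kin-3, 637 in prde-1 and 636 in prg-1, and none rose. The summed level of that cluster was 267-fold lower in kin-3 (95% counting interval 197 to 373), 578-fold lower in prde-1 (507 to 661) and 236-fold lower in prg-1 (191 to 295). On chromosome IV at 4.5 to 7 Mb, 44 of 45 fell in each mutant and the exception was 21ur-1430. Of the 12 tested piRNAs on other chromosomes, 1 fell and 2 rose in kin-3, 2 fell and 5 rose in prde-1, and 1 fell and 3 rose in prg-1; adjusted over the list alone, the counts were 0 and 2, 2 and 4, and 1 and 1. These 12 summed to 72.4 RPM in WT and 143, 135 and 142 RPM in kin-3, prde-1 and prg-1; without 21ur-9719 they summed to 59.0 RPM in WT and 63.4, 106 and 50.2 RPM. Their median log2 fold changes were 0.14, 0.91 and -0.35, against -3.11, -3.11 and -3.10 for the large cluster. The filter on the mean of all 8 libraries favours loci that rise or keep mutant reads. 21ur-15587 (0.372 RPM in WT), 21ur-13684 (0), 21ur-12937 (0.920), 21ur-9823 (1.47), 21ur-12864 (2.19) and 21ur-8285 (3.15) passed it only through their mutant levels. The sums, medians and list tests of the 12 thus partly reflect the filter. Without the filter the medians were -0.10, 0.00 and -0.40 over 45 loci, against -0.93 in each mutant over 4135 of the large cluster. With piRNAs under the floor set to it, the medians of the 12 were 0.41, 0.87 and 0.48, against -1.25, -4.85 and -2.14 for the large cluster. These are upper limits: 4 of the 12 had no prg-1 read and 7 had 1 to 3 kin-3 reads, so the positive sign in prg-1 comes from the floor. With TMM rescaling the prg-1 median turned from -0.35 to 0.05. That of prde-1, whose levels TMM raises against the others, was 3.72, with 9 of the 12 higher. Camera placed the 12 above the other tested piRNAs in each mutant (adjusted p 1.1e-48, 4.0e-53 and 1.4e-42; adjusted p = 5.9e-04 with an estimated correlation in each). The tested piRNAs outside the large cluster are only these 12 and the 45 at 4.5 to 7 Mb. Its test is therefore not independent of that of the 12. Camera placed the large cluster below the others (adjusted p 2.3e-10, 1.9e-11 and 1.2e-09, and 0.0043 in each with an estimated correlation). With the estimated correlation this call ended in kin-3 and prg-1 without WT replicate 1 (0.0713 each) or WT replicate 2 (0.0700 each). The direction of the 12 against WT was not settled. Fry gave a rise in kin-3 and prde-1 (adjusted p = 0.0161 and 0.0078) and none past the threshold in prg-1 (0.423), where it gave a rise without WT replicate 2 (0.0363) and at a mean of at least 10 RPM (6.0e-05, 3 loci). Without the filter, where 45 loci are tested, it gave a fall in kin-3 and prg-1 (0.0150 and 0.0040) and no call in prde-1 (0.367). Without kin-3 replicate 1 it gave a fall in kin-3, prde-1 and prg-1 (0.0128, 0.0032 and 4.8e-04), and without kin-3 replicate 2 a fall in the latter 2. No piRNA on the rest of chromosome IV was abundant enough to be tested.

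The annotated host made less difference than position. Of 444 tested piRNAs outside coding genes, 437, 438 and 437 fell in kin-3, prde-1 and prg-1; of 231 in coding introns, 228, 230 and 229 fell; and of 20 in coding exons, 15 fell in each. In kin-3, 2 of the 444 rose and none in the other 2 lists; in prde-1, 3, 1 and 2 rose; in prg-1, 2, none and 1 rose. Adjusted over the list alone these counts were the same. The median log2 fold changes in coding exons were -2.71, -2.71 and -2.76, against -3.10 in introns in each mutant. Camera placed the coding exon list above the other piRNAs (adjusted p 1.6e-06, 3.8e-08 and 2.3e-06; adjusted p = 0.0118, 0.0086 and 0.0118 with an estimated correlation, and 0.0674 and 0.0531 in kin-3 and prg-1 without kin-3 replicate 1), although fry found that it moved down (4.9e-08, 4.9e-08 and 4.2e-08). All 14 of its piRNAs on chromosome IV fell in every mutant and none of its 6 on other chromosomes did, so this result rests on loci that the comparison by position also holds. Coding introns (adjusted p 0.973, 0.978 and 0.973), loci outside coding genes (0.327, 0.324 and 0.327) and the cluster at 4.5 to 7 Mb (0.379, 0.339 and 0.371) were not set apart.

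Among the 695 tested piRNAs, the more and the less abundant were called lower alike in number. The filter on the mean leaves out rarer piRNAs, so the lowest group holds only the least abundant of those tested. Where mutant values are near 0, passing the filter needs a WT level well above 1 RPM, which favours a call. Without the filter, 2214 of 4878 piRNAs were called lower in kin-3. In the top of 5 groups of 139 by mean over all libraries (WT median 23.6 RPM), 133, 134 and 133 piRNAs fell in kin-3, prde-1 and prg-1, and in the lowest (WT median 4.42 RPM) 138, 138 and 137 fell. The median log2 fold change shrank from -4.61, -4.59 and -4.61 in the top group to -2.44, -2.37 and -2.44 in the lowest. With most mutant values at 0, this median is set by the WT level and the pseudocount and is no measure of how complete the loss was. Summed over the top group, the level was 4483 RPM in WT and 150, 342 and 162 RPM in the mutants; in the lowest group it was 615 RPM and 3.82, 1.73 and 1.23 RPM. The mean that forms the groups includes the mutants, so loci that rose or kept reads there lie in the top group. Of its level, 21ur-9719 held 79.6 RPM in kin-3 and 92.3 RPM in prg-1, and 21ur-1430 held 226 RPM in prde-1. These sums therefore do not show that abundant piRNAs were lost less completely.

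**Figure D3:**
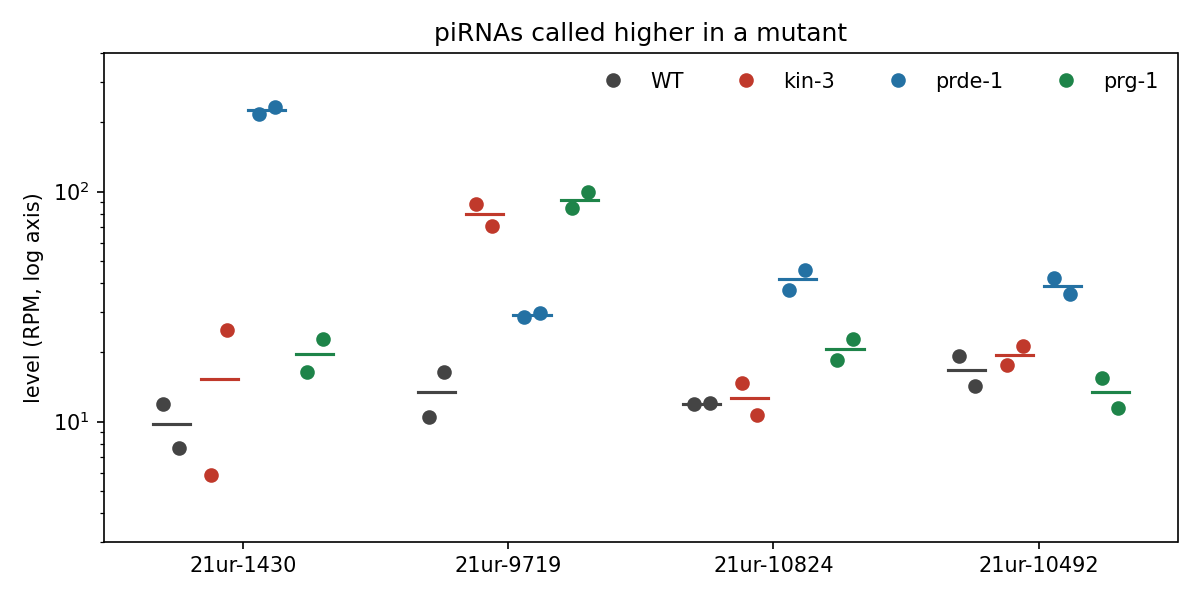
Level of the 4 named loci that were called higher in at least 1 mutant, in RPM on a log axis. Each point is 1 library and each line the mean of 2; 21ur-1430 lies at 218 and 234 RPM in prde-1, and 21ur-9719 lies between 71.2 and 100 RPM in the kin-3 and prg-1 libraries and at 28.5 and 29.6 RPM in prde-1.

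Direct comparison of kin-3 with the reference mutants asks whether its piRNA profile differs from theirs. In the total and on chromosome IV, kin-3 and prg-1 were closest. The total in kin-3 was 0.973 of prg-1 (95% counting interval 0.816 to 1.16), chromosome IV without 21ur-1430 was 0.906 (0.633 to 1.28) and other chromosomes 1.01 (0.810 to 1.25). Without 21ur-9719 the last was 1.27 (0.904 to 1.76), with both kin-3 libraries above both of prg-1. In the prde-1 total of 394 RPM, 21ur-1430 held 226 RPM. Spearman's rho of the changes against WT was lowest for kin-3 and prg-1 (0.976, against 0.985 and 0.988). They also had the fewest piRNA reads, 199 and 378 against 4314 in prde-1, so differences between them could go unseen. Against prde-1, kin-3 had a higher chromosome IV level as a share of the library (pooled level 55.4 against 24.2 RPM, ratio 2.29, interval 1.66 to 3.10); its libraries lay at 79.2 and 40.9 RPM, a wider gap than counting error gives (exact binomial p = 0.0198), so the interval is too narrow. The ratio for other chromosomes was 1.02 (0.850 to 1.22), the sum of opposite differences: 2.67 for 21ur-9719 (2.03 to 3.47) and 0.607 for the rest (0.463 to 0.781). The prg-1 level on chromosome IV was 2.52 times that of prde-1 (1.99 to 3.18). These ratios cover counting error only, since 2 libraries against 2 cannot give an exact p under 0.333. Among single piRNAs limma called none of the 695 in any of the 3 pairs (8, 5 and 9 at an unadjusted p under 0.05 for kin-3 against prde-1, kin-3 against prg-1 and prde-1 against prg-1). edgeR on the recovered reads called 3, 0 and 5. In kin-3 against prde-1 these were 21ur-1430 and 21ur-10824, lower in kin-3, and 21ur-9719, higher in kin-3. In prde-1 against prg-1 they were 21ur-1430, 21ur-10824, 21ur-10492 and 21ur-15587, higher in prde-1, and 21ur-9719, lower.

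The changes against WT were alike across piRNAs. Pearson's r of the log2 fold changes over the 695 piRNAs, which are not independent replicates, was 0.969 for kin-3 and prde-1 (Spearman's rho 0.985), 0.975 for kin-3 and prg-1 (0.976) and 0.973 for prde-1 and prg-1 (0.988). Unchanged groups drawn from the pooled levels of the same WT libraries gave r of 0.0608, 0.0386 and 0.0949. This simulation did not redraw WT, so it leaves out WT counting error and is no measure of what the shared controls add. The covariance was 1.15, 1.09 and 1.12, against simulated values of 0.00648, 0.00989 and 0.00671. With nearly all mutant values at 0, these correlations follow the WT level. All 3 mutants shared 678 of the lower calls, where lists independent of each other would share 655. Of the rises, 21ur-9719 and 21ur-9823 were called in all 3, and 21ur-10824 in prde-1 and prg-1. Those of 21ur-9823 in prde-1 and prg-1 and of 21ur-10824 in prg-1 ended under edgeR, so by edgeR only 21ur-9719 rose in all 3. The 2 WT libraries could not be split with 2 in each part, so part of the likeness can come from the shared controls.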

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

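All tests of explanations in this part were chosen after the results were seen, while edgeR had been chosen before the data were examined. Direct differences between mutants past the edgeR threshold drew attention to 5 loci. Limma on the 695 piRNAs and 8 libraries, with pseudocount 1 and no rescaling, called none of them between mutants. With TMM rescaling, which raises prde-1 levels against all other libraries, it called 4 of them. At a mean of at least 10 RPM, where 31 are tested, it made the same calls as edgeR except 21ur-15587, whose mean was lower. In kin-3 against prde-1 the edgeR log2 difference was -3.67 for 21ur-1430 (edgeR adjusted p = 1.6e-25, limma adjusted p = 0.346), -1.77 for 21ur-10824 (0.0062 and 0.291) and 1.42 for 21ur-9719 (2.5e-05 and 0.598). In prde-1 against prg-1 it was 3.55 for 21ur-1430 (4.0e-38 and 0.359), 1.03 for 21ur-10824 (0.0434 and 0.472), 1.497 for 21ur-10492 (6.1e-04 and 0.228), -1.65 for 21ur-9719 (3.9e-13 and 0.256) and 6.73 for 21ur-15587 (0.0020 and 0.877). In each of these the 2 libraries of one genotype lay beyond both of the other.

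21ur-1430 was 23.0-fold higher in prde-1 than in WT. The levels are shares of each library, so the greater depth in prde-1 changes their counting error and not their expected size; the pooled ratio to WT was 22.2 (95% counting interval 14.7 to 35.01). A candidate source of its reads is the mir-790 arm on the same strand, whose annotated ends lie 1 and 0 nt away. Reads of the microRNA cannot be told apart from a change of the piRNA itself. 21ur-1430 drew attention because it did not fall like the other 44 tested piRNAs of the cluster at 4.5 to 7 Mb, so that is no test, and the other 3 listed piRNAs on microRNA precursors of the same strand had 1 WT read in all, too few to decide. Its log2 fold change in kin-3 was 0.33, but -0.62 without kin-3 replicate 2 and 1.29 without replicate 1. Why the level rose in prde-1 and not past the threshold in kin-3 or prg-1 stays open: strain, stage of the worms and library batch were not given by the labels, and an effect of prde-1 on this locus was not tested.

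The 12 tested loci on other chromosomes were not lost as a group, although 4 of them had no read in prg-1. The filter favours loci that keep mutant reads. The 12 summed to 72.4 RPM in WT and to 143, 135 and 142 RPM in kin-3, prde-1 and prg-1. Without 21ur-9719 they summed to 59.0 RPM in WT and to 63.4, 106 and 50.2 RPM. If they were piRNAs bound by PRG-1 and made without the upstream complex, they would fall in prg-1. The pooled level of 21ur-9719 in prg-1 was 7.08 times that in WT (95% counting interval 4.74 to 10.9). This locus was singled out because it rose, so that is no test. For the list this explanation cannot be told apart from other sources of the reads. Over the 109 listed loci on other chromosomes the pooled level in prg-1 was 1.67 of WT (1.37 to 2.02), and without 21ur-9719 it was 0.736 (0.564 to 0.954), so 1 locus turns the direction, and the 12 tested loci moved both ways (log2 fold changes from -3.16 to 2.72). Another possible explanation is reads of other RNAs at the same positions. Of the 12, 3 overlap an annotated exon on the same strand and 8 only one on the opposite strand, against an overlap on either strand at 2.64% of tested chromosome IV loci. On chromosome IV, of the loci with one, 21ur-1430 set aside, 17 of 17 fell in every mutant, and 4 of 665 without one did not (exact Fisher p = 1); with 21ur-1430 it was 1 of 18 against the 4 of 665 (p = 0.125). At the 8 loci the overlapping transcript lies on the opposite strand, so its own reads would not carry the piRNA's strand. How strand was treated when reads were assigned is not given in the sources used here. The levels of the overlapping transcripts and of small RNAs antisense to them were not analysed here. Reads of other RNAs therefore cannot be told apart from a property of these loci.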

How the results depend on the processing

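The loss of piRNAs kept its direction under every alternative run. The numbers called lower were within 1.5 times of those reported with pseudocounts of 0.1 and 5, TMM rescaling, edgeR on recovered reads, only the genotypes compared, and each library left out (672 to 680 in kin-3, 678 to 683 in prde-1 and 677 to 683 in prg-1). Testing more or fewer piRNAs changed them: without the filter (4878 tested) 2214, 2216 and 2208 were lower in kin-3, prde-1 and prg-1, and at a mean of at least 10 RPM (31 tested) 27 in each, with 1 higher in kin-3. TMM rescaling gave 10 higher in prde-1, and leaving out single libraries gave 2 to 4 higher in kin-3, 3 to 6 in prde-1 and 1 to 3 in prg-1. These were 4 in kin-3 without either kin-3 library, 3 in prde-1 without either prde-1 library, and 1 in prg-1 without WT replicate 1 or prg-1 replicate 2. With 1 library left, its spread is assumed to be that of the other genotypes. TMM rescaling moved the median log2 fold change of the tested piRNAs to -2.15, -2.12 and -2.14, with 27 to 85 piRNAs shared by a mutant library and WT replicate 1. edgeR called 675, 683 and 683 lower and 2, 6 and 2 higher. Its higher calls in prde-1 and prg-1 included 21ur-13684, without a WT read, which the main limma fit did not call. Without 21ur-1430 and 21ur-9719, chosen after seeing the data, 1 was higher in kin-3.

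Replicate numbers are shared by the labels. The correlations of the deviations of samples with the same number ranged from -0.029 to 0.074. Of the 695 piRNAs, 617, 662 and 663 had no read in prde-1, prg-1 and kin-3, so most mutant deviations are 0. These correlations therefore cannot show whether such samples deviated together. With the replicate block, limma called 680, 682 and 682 lower and 2, 6 and 2 higher; 21ur-9823 was not called in prde-1 and prg-1 (adjusted p = 0.0706 and 0.0708), and 21ur-13684 was in prde-1. edgeR with the replicate block, chosen after seeing the data, called 125 lower and 1 higher in kin-3, 682 and 6 in prde-1, and 259 lower and 1 higher in prg-1. Its median log2 fold changes were -6.91, -6.82 and -6.88, against -6.90, -6.82 and -6.89 by edgeR without it, so calls were lost and the size of the change was not. Between mutants it called 2 lower and 1 higher for kin-3 against prde-1, and 1 lower and 2 higher for prde-1 against prg-1, where 21ur-10824 and 21ur-15587 were not called and 21ur-1430, 21ur-10492 and 21ur-9719 were.

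Between mutants, where limma called 0, the alternatives called a few. For kin-3 against prde-1, edgeR called 2 lower and 1 higher, a mean of at least 10 RPM 2 and 1, TMM rescaling 6 lower, pseudocount 0.1 gave 1 lower, and single libraries left out 0 to 2 lower and 0 to 8 higher (8 without kin-3 replicate 2, 5 without replicate 1). For kin-3 against prg-1, pseudocount 0.1 gave 1 lower, and libraries left out 0 to 2 lower and 0 to 7 higher (7 without kin-3 replicate 2, 6 without replicate 1). For prde-1 against prg-1, edgeR called 1 lower and 4 higher, a mean of at least 10 RPM 1 and 3, TMM rescaling 5 higher, pseudocount 0.1 gave 1 and 1, and libraries left out 0 to 2 lower and 0 to 2 higher. At a mean of at least 10 RPM the calls were those of edgeR apart from 21ur-15587, which was not tested there. With TMM rescaling 21ur-1430, 21ur-10824, 21ur-10492 and 21ur-15587 were called in both pairs with prde-1 and 21ur-9719 in neither. TMM factors of 0.176 and 0.144 in prde-1, against 1.08 to 2.22 in the other libraries, raise prde-1 in both pairs. Why the other alternatives differed was not tested. With only the 2 mutants compared, limma's trended fit stopped, since 602, 640 and 599 of the 695 piRNAs had no read in any of the 4 libraries (kin-3 and prde-1, kin-3 and prg-1, prde-1 and prg-1). Limited to the 93, 55 and 96 piRNAs with a read in either, chosen after seeing the data, that fit called 1 lower and 1 higher, none (1 at an unadjusted p under 0.05; edgeR 0), and 1 lower and 4 higher.

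Totals as a percentage of WT moved with the loci summed. For prde-1, prg-1 and kin-3 they were 16.7%, 7.39% and 6.47% over piRNAs with a mean of at least 10 RPM, and 0.473%, 0.640% and 0.785% without the 10 most abundant; on chromosome IV without 21ur-1430, chosen after seeing the data, they were 0.185%, 0.457% and 0.459%. At a mean of at least 10 RPM, 21ur-1430 held 226 of 335 RPM in prde-1. There 21ur-9719 held 92.3 of 148 RPM in prg-1 and 79.6 of 130 RPM in kin-3. These percentages thus do not give what abundant piRNAs in general kept. Numbers detected were 17.7%, 17.7% and 16.1% of WT at a mean of at least 10 RPM, where the exact permutation p over the 4 genotypes was 0.143. Without the 10 most abundant, prde-1 was at 3.53% and kin-3 at 0.912%; on chromosome IV without 21ur-1430 at 2.93% and 0.644%; thinned to 341001 reads, also chosen later, at 1.03% and 1.63%; and with single libraries left out at 3.37% to 3.99% and 0.943% to 1.12%. The exact permutation p of WT against the rest ranged from 0.0476 to 0.143 with 1 library left out, for totals and for numbers detected; with 1 WT library 0.143 is the smallest possible.

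The 18 list tests by camera gave the same call in 249 of 252 alternatives, all but 18 of them at the preset correlation; without the filter the cluster at 4.5 to 7 Mb passed in kin-3, prde-1 and prg-1 (adjusted p 0.0164, 0.0189 and 0.0164), with more piRNAs tested, but not with an estimated correlation as well (0.0679, 0.0690 and 0.0679); its highest adjusted p over the alternatives was 0.812, 0.899 and 0.812. With the estimated correlation in every setting, chosen after seeing the data, 8 of 234 calls ended. These were the large cluster in kin-3 and prg-1 without WT replicate 1 (0.0713 each) or WT replicate 2 (0.0700 each), and coding exons in kin-3 and prg-1 at a mean of at least 10 RPM (0.0766 and 0.0861) and without kin-3 replicate 1 (0.0674 and 0.0531). For the loci on other chromosomes the fry call in kin-3 ended with TMM rescaling (adjusted p = 0.232), without 21ur-1430 and 21ur-9719 (0.466, chosen after seeing the data) and without prg-1 replicate 1 or 2 (0.0570 each) or kin-3 replicate 2 (0.0563). With the replicate block that in prde-1 ended (0.0666). The piRNAs named by the rule fixed beforehand kept their call in 735 of 750 alternatives, 11 lost it and 4 gained it, and none reversed. The calls lost were all rises, of 21ur-9719 in each mutant and of 21ur-10824 in prg-1, and those gained were of 21ur-1430. Falls to few or no mutant reads made up most of the others, so the share kept says little about the rises. These counts leave out 21ur-9823 and 21ur-15587. Their rises in prde-1, and that of 21ur-9823 in prg-1, ended under several alternatives. With pseudocount 0.1 the median log2 fold changes of the 5 abundance groups were -7.86, -6.89, -6.28, -5.79 and -5.50 in kin-3 and in prg-1, and -7.81, -6.86, -6.26, -5.79 and -5.41 in prde-1, since most mutant values are 0. Pearson's r at a mean of at least 10 RPM was 0.958 for kin-3 and prde-1, 0.989 for kin-3 and prg-1 and 0.967 for prde-1 and prg-1; with single libraries left out r was 0.937 to 0.972 for kin-3 and prde-1, 0.951 to 0.978 for kin-3 and prg-1, and 0.967 to 0.976 for prde-1 and prg-1; and without 21ur-1430 and 21ur-9719 it was 0.980 for prde-1 and prg-1. Lists on the upstream motif could not be run without a genome sequence, and the size-factor alternative applies only to counts. Depth limits kin-3 most: a piRNA at the median WT level with no kin-3 read is bounded only at 2.33-fold lower, against 28.2-fold in prde-1 and 4.30-fold in prg-1.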

Other observations

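In WT the listed piRNAs came mostly from the large cluster. Loci on chromosome IV from 13 Mb gave 91.9% of the WT piRNA level, those at 4.5 to 7 Mb 7.27%, the rest of chromosome IV 0.162% and other chromosomes 0.670%. A read was found in at least 1 WT library for 4077 of 8018 listed loci of the large cluster (50.8%), for 655 of 1512 of the small one (43.3%), for 25 of 103 on the rest of chromosome IV (24.3%) and for 30 of 109 elsewhere (27.5%). Loci outside coding genes gave 62.2% of the WT level, coding introns 34.9% and coding exons 2.88%. The mean WT level per listed locus was 1.41 RPM in introns, 1.35 RPM outside coding genes and 0.944 RPM in exons. The 5 highest piRNAs held 4.98% and 5.12% of the piRNA level in the WT libraries, against 57.3% and 66.7% in kin-3, 86.2% and 87.4% in prde-1 and 62.2% and 71.8% in prg-1. Of the 9742 listed piRNAs, 4864 had no read in any library.

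Loci on other chromosomes differed among themselves. 21ur-9719 held 40.9% of all listed piRNA reads by level in prg-1 and 35.5% in kin-3, against 7.37% in prde-1 and 0.102% in WT. Without it, the other 108 loci summed to 74.8 RPM in WT, 69.3 in kin-3, 115 in prde-1 and 54.2 in prg-1. 21ur-12557 (V 17156026 to 17156046, antisense to the 3′ UTR of F40D4.13) fell from 7.93 RPM to 0.548 in prde-1 and to 0 in prg-1 (limma adjusted p = 0.0018 and 6.8e-04), and stood at 3.82 RPM in kin-3 (0.0550); kin-3 against prg-1 had an unadjusted limma p of 0.0035 and an adjusted p of 0.811. 21ur-10895 (V 12386732 to 12386752) fell in prde-1 to 1.01 RPM from 8.70 (adjusted p = 0.0083) and stood at 5.04 in prg-1 and 4.71 in kin-3.

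The tests in this paragraph were chosen after the reads were seen. A few chromosome IV reads outside 21ur-1430 remained in each mutant: 135 and 130 in prde-1, 66 and 36 in prg-1, and 27 and 23 in kin-3. Reads carried over from the WT libraries, for instance by barcode misassignment, would fall on loci that WT covers. In WT replicate 2, 10.6% of these reads lay at loci without a read in WT replicate 1. The share was 34.3% in prde-1 (exact 95% interval 28.6 to 40.4) and 36.3% in prg-1 (27.0 to 46.4), which argues against carry-over from these WT libraries as the whole source there; in kin-3 it was 16.0% (7.17 to 29.1) and cannot be told apart from it, since 50 reads are too few. Drawn at random from the WT levels, as many reads would reach 213 to 237 loci in prde-1, 89 to 100 in prg-1 and 45 to 50 in kin-3 (95% of 1000 draws); they reached 195, 95 and 44. This count gives another order of the mutants than the share, and since it rests on an assumed profile it excludes nothing. Remaining production in the mutants, reads of other RNAs at these positions and carry-over from libraries not analysed here may each account for them, and were not tested.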
